A study of Homo sapiens with 16 samples.

How the data were processed

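Gene expression had been measured on 16 Affymetrix U133 2.0 arrays, each with 22277 probe sets, in 8 groups of 2 arrays. Per the labels, the groups are MDA-MB-231 and LM24175 with empty vector or RECK construct, and Hs343T and Hs606T with scrambled siRNA or an siRNA against RECK. The deposited table holds log2 values per probe set and array, made by the authors from scanner files imported into Partek per the submitters' processing notes. The version and the method of summary and scaling are not given in the sources used here. The log base was read from the values, whose array medians lay between 6.42 and 6.57. No values were rescaled or filtered. No detection calls and no scanner files were used here.

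Probe sets were joined to genes through the platform annotation. Of 22277 probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 were not listed there. After the 62 control probe sets of the table were left out, 19064 probe sets with exactly 1 symbol gave 11963 genes, and 4310 genes had over 1 probe set. Each gene was read from the probe set with the highest mean over the 16 arrays, and 460 genes were measured only by cross-hybridising probe sets. For 19052 of these probe sets the gene identifier matched the current gene table, and 0 symbols needed updating. Members of gene lists with no such probe set were not analysed here.

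All 16 arrays entered 1 fit of 8 group means with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with 8 residual and 3.72 prior degrees of freedom and a median residual SD of 0.129 log2 units. The 10 comparisons were construct minus empty vector in each invasive line and over both, siRECK minus siSCR in each poorly invasive line and over both, the mean of all 4 in the direction of the RECK labels, the difference between the 2 responses within each kind of treatment, and LM24175 minus MDA-MB-231 with empty vector. Tests were 2-sided, p-values were adjusted by Benjamini and Hochberg over the genes of a comparison, and an adjusted p under 0.05 passed. Intervals are 95% intervals of the moderated fit. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

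The groups, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined. By that rule, the text names RECK, the 10 largest rises and 10 largest falls of each line comparison among passing genes whose groups of arrays do not overlap, the 8 largest in each direction in the other comparisons, up to 4 passing members of each described list, and 10 genes of the STAT3 and invasion question whatever their values. Of 29 gene lists, 14 are described under Results, and Other observations gives values of further lists. Which lists are described in which comparison was chosen and trimmed after the list results were seen. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list moves one way and does not compare it with other genes. Of 38 pairs of list and comparison tallied, 24 passed camera and 7 also passed with an estimated correlation. With fry in place of camera, 7 of the 24 lost the call and 2 other pairs gained it. Outside this tally lie the pairs given for the differences between responses, some over both invasive lines and those under Other observations. Of these, the lipid list between the invasive responses and the interferon list between the siRNA responses also passed both ways.

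The alternatives were quantile normalization, centring of each array on its median, the mean of all probe sets of a gene, every probe set tested alone, leaving out the genes in the lowest 0.25 of level, eBayes with trend and robust, only the arrays compared, replicate number as a block, a 1.5-fold minimum, and leaving out each array in turn. The sign of the siRNA lines turned, leaving out Hs343T, and leaving out both arrays that deviate together were added after the data were seen. The procedure was tested on simulated data with 200 changed genes per line comparison. It recovered from 64.0% to 72.0% of 1.5-fold changes, from 92.0% to 94.0% of 2-fold changes and 100% of 4-fold and 8-fold changes, with 7 to 16 false calls in a comparison and 0 calls where nothing was changed. Of changes of at least 2-fold, 99.5% were recovered in the means over 2 lines and 94.3% and 94.6% in the differences between responses. A list moved in the simulation was called by camera (adjusted p = 4.64e-55) and by fry (adjusted p = 2.0e-06), with 0 other lists called. Simulated noise was independent between genes and arrays and had the same spread in every group. It held no correlation within lists and no arrays that deviate together. These rates may therefore be better than on the real arrays, and the simulation cannot judge the preset correlation.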

Results

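Gene expression was measured on 16 Affymetrix U133 2.0 arrays of 4 human breast cell lines, with 2 arrays in each of 8 groups. The series asked what RECK, a membrane-anchored inhibitor of matrix metalloproteinases, does to expression in lines of different invasiveness. MDA-MB-231 and LM24175, a lung-metastatic derivative of MDA-MB-231, are described as invasive and carried a RECK construct or an empty vector. Hs343T and Hs606T are described as poorly invasive and received an siRNA labelled as targeting RECK (siRECK) or a scrambled siRNA (siSCR). Array medians lay between 6.42 and 6.57 log2 units, and the correlation between the arrays of a group ran from 0.994 to 0.998 across probe sets. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value below. Differences are log2 values of the first group minus the second, and 11963 genes were tested in each comparison.

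RECK itself went against the siRNA labels. Of its 3 probe sets, the one with the highest level read 5.80 ± 0.39 (SD, n = 2) on the Hs343T arrays labelled siSCR and 11.27 ± 0.05 (SD, n = 2) on those labelled siRECK. RECK was thus 44.5-fold higher on the arrays labelled siRECK (95% interval 35.1 to 56.6; log2 difference 5.48, SE 0.16; adjusted p = 1.28e-10). In Hs606T the levels were 8.69 ± 0.06 (SD, n = 2) and 11.09 ± 0.10 (SD, n = 2), a 5.29-fold higher level on the arrays labelled siRECK (95% interval 4.16 to 6.71; adjusted p = 6.65e-06). The rise was smaller in Hs606T by a log2 difference of -3.07 (SE 0.22; adjusted p = 1.32e-06). A further RECK probe set, open to cross-hybridisation, was higher by 0.46 in Hs343T (adjusted p = 0.0016), while its difference of 0.17 in Hs606T did not pass (adjusted p = 0.514). The remaining one differed by 0.27 in Hs343T (adjusted p = 0.1999) and by -0.10 in Hs606T (adjusted p = 0.862). In the lines with the construct no RECK probe set passed. The first differed by 0.03 (SE 0.16; adjusted p = 0.962) in MDA-MB-231 and by -0.42 (SE 0.16; adjusted p = 0.154) in LM24175. Where these probe sets lie relative to the sequence in the construct is not known here, so they may not check it. The siRNA arms are called the arrays labelled siRECK and siSCR throughout, and each direction drawn from them is that of the labels, opposite to the RECK level measured.

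**Figure D1:**
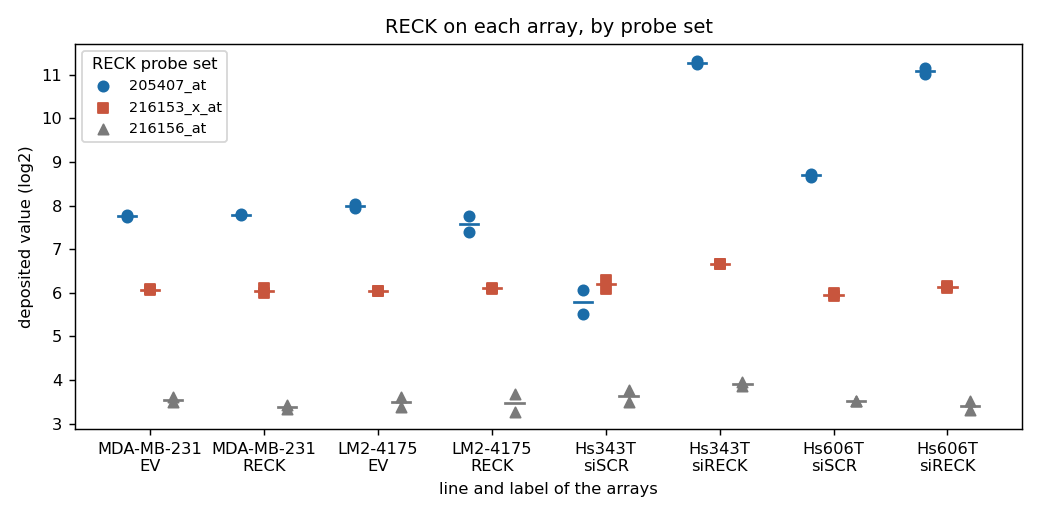
RECK level on each of the 16 arrays (deposited log2 value, vertical axis) by line and label (horizontal axis), with 1 symbol per array, 1 marker type per RECK probe set and a bar at each group's mean. On the probe set with the highest level the arrays labelled siRECK lie near 11.27 in Hs343T and 11.09 in Hs606T, above the arrays labelled siSCR at 5.80 and 8.69.

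In MDA-MB-231, cells with the RECK construct had more transcripts of IL1B, CXCL3 and CXCL1 than cells with the empty vector. IL1B, which encodes interleukin-1 beta, rose 4.25-fold (95% interval 2.74 to 6.61; log2 difference 2.09, SE 0.29, n = 2 and 2; adjusted p = 0.0174). The neutrophil-attracting chemokines CXCL3 and CXCL1 rose by 1.68 (SE 0.26; adjusted p = 0.0291) and 0.98 (SE 0.14; adjusted p = 0.0174). The other largest rises were in SSX1 and SPANXB1, cancer-testis genes, at 1.62 and 0.85, in S100P, a calcium-binding protein, at 1.51, in TMEM47 at 1.14, in PSAT1, an enzyme of serine synthesis, at 0.95, in PTPRN2, whose probe sets differed in sign, at 0.93 and in ENPP2, the enzyme autotaxin, at 0.85. All 6 genes that fell can be named: CD96 (-1.07), ADIRF (-0.82), the small heat shock protein gene HSPB8 (-0.78), VSNL1 (-0.75), the calcium pump gene ATP2B4 (-0.69) and C15orf39 (-0.48). In all, 33 genes passed (27 higher, 6 lower), 25 of them by at least 1.5-fold. For each gene named among the largest changes, here and in the other line comparisons, both arrays of one group lay beyond both arrays of the other.

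Genes of cholesterol and lipid synthesis rose together in MDA-MB-231 with the construct. Of 22 measured, 4 rose and none fell, and 12 rose when adjusted over the list alone. These were MSMO1 (0.77), INSIG1 (0.73), SC5D (0.65) and DHCR7 (0.52), and the list stood above other genes (camera adjusted p = 7.83e-13; adjusted p = 0.0208 with an estimated correlation). In the list of NF-kB targets and inflammatory cytokines, 3 of 31 rose, or 9 when adjusted over the list alone, and the camera call (adjusted p = 5.79e-08) was lost at adjusted p = 0.461 with an estimated correlation. Among targets of the unfolded protein response and of ATF4, 2 of 34 rose, PSAT1 and MTHFD2 (0.62), or 18 when adjusted over the list alone, with camera adjusted p = 5.03e-12 and adjusted p = 0.439 with an estimated correlation. The same 3 cytokine genes, IL1B, CXCL3 and CXCL1, were the members that rose among 47 pro-angiogenic factors, with 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0494; adjusted p = 0.669 with an estimated correlation). No cell cycle gene of 59 passed, nor when adjusted over the list alone, although the list lay lower at a median of -0.19 (camera adjusted p = 7.07e-08; adjusted p = 0.669 with an estimated correlation). Without the first empty-vector array the camera p of the cell cycle list was 0.924 and that of the pro-angiogenic list 0.574, and the latter was 0.243 without the second RECK array and 0.0611 without dim genes. No STAT3 target of 33 passed (0 when adjusted over the list alone; camera adjusted p = 0.102, against 9.84e-04 without the second empty-vector array and 0.0149 without the first RECK array). The 10 genes fixed in advance for the STAT3 and invasion question did not pass. STAT3 differed by -0.02, IL6 by 0.62, IL6ST by 0.19, VEGFA by 0.29, CXCL8 by 1.19, PLAU by -0.11, MMP1 by 0.44, MMP2 by -0.25, MMP9 by 0.28 and MMP14 by 0.11, with the smallest adjusted p at 0.132 for CXCL8.

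The MDA-MB-231 result depended on single arrays. With its own 4 arrays alone, limma called 0 genes. An unadjusted p under 0.05 was reached by 685 of 11963, little above the share of 0.05 expected if no gene changed. Of 21 named genes that passed, 20 lost the call when 1 array was left out. Leaving out an array gave 681 genes without the second empty-vector array, 3 without the first RECK array and 119 without the second RECK array. The first empty-vector array and the first RECK array of LM24175 deviated together from their replicates (r = 0.486 across genes, which are not independent replicates). On that empty-vector array IL1B lay 0.67 log2 units below its replicate (difference -0.67), CXCL3 -1.03, CXCL8 -0.97, VEGFA -0.77 and PLAU -0.99. Without both arrays, 117 genes passed, 24 of them among the 33, with IL1B at 1.75 and CXCL3 at 1.16, while the camera calls of the cell cycle (adjusted p = 0.990) and pro-angiogenic lists (adjusted p = 0.109) ended.

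In LM24175, cells with the construct had more transcripts of COL1A2, COL3A1, MMP1, MMP3 and MMP9. COL1A2, a chain of collagen I, rose 4.61-fold (95% interval 2.97 to 7.15; log2 difference 2.20, SE 0.29, n = 2 and 2; adjusted p = 0.0011) and COL3A1, the chain of collagen III, by 1.52 (SE 0.19; adjusted p = 7.64e-04), although its probe sets differed in sign. The COL3A1 level with empty vector lay below the lower quartile of those arrays (4.51 and 4.47). A level that low cannot be told from background here. MMP1, an interstitial collagenase, rose 3.41-fold (95% interval 2.75 to 4.23; adjusted p = 9.87e-05), with the stromelysin gene MMP3 at 1.61 and the gelatinase gene MMP9 at 1.09 (adjusted p = 0.0149). Further large rises were in TCN1 (1.70), TENM1 (1.66), ENPP2 (1.66), HMGN5 (1.65), the aldo-keto reductase AKR1C1 (1.585) and LYPD1 (1.499). The largest falls were in LOXL1, a collagen cross-linking oxidase (-2.175), SHANK2 (-2.08, probe sets differing in sign), the transporters SLCO4C1 (-1.77) and ABCC3 (-1.67), the fatty acid binding protein FABP4 (-1.65), HLA-DPA1 (-1.64), the fatty acid desaturase SCD (-1.56), C4BPB (-1.53), MIR3916 (-1.43) and AUTS2 (-1.38). In all, 802 genes passed (411 higher, 391 lower), 343 of them by at least 1.5-fold.

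Cholesterol and lipid synthesis moved the other way in LM24175. Of 22 genes 10 fell and 1 rose, or 18 and 1 when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 6.86e-13; adjusted p = 0.0205 with an estimated correlation). SCD, the fatty acid synthase FASN (-1.08), HMGCS1 (-0.79) and DHCR7 (-0.77) fell most. In the list of MMPs, ADAMTS proteases and TIMPs, 4 of 24 rose and none fell, MMP1, MMP3, MMP9 and ADAMTS1 (1.015), while 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.181). Matrix genes moved both ways, with 4 of 44 higher and 5 lower (6 and 7 when adjusted over the list alone; camera adjusted p = 0.934). They included COL1A2, COL3A1 and COL6A3 (1.36) on one side and LOXL1 on the other. Among 21 genes of oxidative stress and metallothioneins 4 rose and 3 fell, or 4 and 7 when adjusted over the list alone (camera adjusted p = 0.798), led by AKR1C1, AKR1C2 (1.39, measured only by cross-hybridising probe sets), AKR1C3 (1.18) and HMOX1 (0.64). Of 31 NF-kB targets the cytokine genes IL11 (-1.30) and CSF1 (-0.81, probe sets differing in sign) fell, in the list alone too (camera adjusted p = 0.122). MMP9 was the 1 STAT3 target of 33 to rise, also when adjusted over the list alone (camera adjusted p = 0.788). Of 47 pro-angiogenic factors HBEGF (0.34) and PDGFC (0.25) rose and FGF1 (-0.40, probe sets differing in sign) fell, or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.798). Of the remaining genes fixed in advance none passed: STAT3 differed by -0.11, IL6 by -0.12, IL6ST by -0.12, VEGFA by -0.40, CXCL8 by -0.29, PLAU by -0.35, MMP2 by -0.36 and MMP14 by 0.37.

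For LM24175, 153 genes passed with its own 4 arrays alone. Of 36 named genes that passed, 11 lost the call when 1 array was left out. Over all genes 276, 290 and 447 passed without the first empty-vector, the second empty-vector and the first RECK array. On that RECK array IL1B lay -1.19 from its replicate, VEGFA -1.05, CXCL8 -0.79, PLAU -0.72 and CXCL3 -0.64. Without it and the deviating MDA-MB-231 array 965 genes passed, 559 of them among the 802. MMP9, FGF1 and PDGFC then no longer passed, MMP14 did (0.49, adjusted p = 0.0073), and so did the camera tests of the lists of MMPs (adjusted p = 0.0456), STAT3 targets (0.0072) and pro-angiogenic factors (0.0476). The STAT3 target list also passed without the first RECK array alone (adjusted p = 0.0329), and the NF-kB list without the second RECK array (adjusted p = 1.56e-05) and with each array centred on its median (adjusted p = 0.0459), where 477 genes were higher and 302 lower.

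In Hs343T, transcripts of the interferon response were far higher on the arrays labelled siRECK than on those labelled siSCR. The interferon-induced chemokine CXCL11 was 565-fold higher (95% interval 269 to 1186; log2 difference 9.14, SE 0.49, n = 2 and 2; adjusted p = 3.55e-08), and the antiviral gene RSAD2 520-fold (95% interval 430 to 629; log2 difference 9.02, SE 0.13; adjusted p = 2.16e-13). IFNB1, which encodes interferon beta, rose by 8.50 (SE 0.11; adjusted p = 1.55e-13), from 4.26 ± 0.05 to 12.76 ± 0.05 (SD, n = 2). Next came the chemokine CXCL10 (8.56), the antiviral genes MX1 (8.16), IFIT1 (7.94), IFI44L (7.56) and OASL (7.26), the RNA sensor IFIH1 (7.69) and the death ligand TNFSF10 (7.29). All 38 measured interferon-stimulated genes rose, with a median of 5.97, and all 38 when adjusted over the list alone (camera adjusted p = 8.1e-60; adjusted p = 0.0019 with an estimated correlation). The largest falls were in the ceramide kinase CERK (-3.55), the p53 target ZMAT3 (-3.34), the urokinase gene PLAU (-3.14), NT5DC2 (-2.87), ADGRA3 (-2.81), CNIH3 (-2.805), the spindle checkpoint kinase BUB1B (-2.78), the cystine transporter SLC7A11 (-2.76), FAM171A1 (-2.62) and CPEB1 (-2.61).

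Cell cycle genes fell in number in Hs343T on the arrays labelled siRECK. Of 59, 47 fell and none rose, or 52 when adjusted over the list alone, led by BUB1B, DLGAP5 (-2.41), TOP2A (-2.29) and CDK1 (-2.16). The camera call (adjusted p = 4.29e-19) was lost at adjusted p = 0.394 with an estimated correlation. Of 31 NF-kB targets and cytokines 18 rose and 2 fell, or 19 and 2 when adjusted over the list alone (camera adjusted p = 9.62e-09; adjusted p = 0.394 with an estimated correlation). CCL5 (6.17), VCAM1 (3.37), CSF1 (3.03, probe sets differing in sign) and CCL2 (2.93) rose most. Among 23 genes of IL-6 family receptors and JAK-STAT signalling 8 rose and 1 fell, as when adjusted over the list alone, with the feedback inhibitors SOCS1 (3.26, probe sets differing in sign) and SOCS2 (1.88), the kinase JAK2 (2.78) and IL6 (1.12) moving most (camera adjusted p = 0.0216; adjusted p = 0.394 with an estimated correlation). STAT3 itself rose by 0.97 (SE 0.09; adjusted p = 6.36e-06). Of 33 STAT3 targets 12 rose and 3 fell, or 13 and 3 when adjusted over the list alone, led by ICAM1 (2.43), FOS (1.72), BIRC5 (-1.68) and JUNB (1.53), with camera adjusted p = 0.0269 and adjusted p = 0.608 with an estimated correlation. Pro-angiogenic factors split, 13 higher and 9 lower of 47, also when adjusted over the list alone (camera adjusted p = 0.0842), with PLAU lower and FGF1 (2.51), the thymidine phosphorylase TYMP (2.06) and EDN1 (1.97) higher. Of 34 targets of the unfolded protein response and of ATF4, 14 fell and 2 rose, the same counts when adjusted over the list alone, with SLC7A11, DDIT4 (-1.97) and TRIB3 (-1.34) lower and ATF3 (2.63) higher (camera adjusted p = 0.0221; adjusted p = 0.608 with an estimated correlation). Of 18 leukocyte markers only CD163 passed (-0.43; 0 when adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.977). VEGFA fell by 0.95 (adjusted p = 0.0245), while IL6ST (0.03), CXCL8 (-0.38), MMP1 (-0.305), MMP2 (0.03), MMP9 (-0.24) and MMP14 (-0.12) did not pass.

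In all, 3511 genes passed in Hs343T (1432 higher, 2079 lower), against 1602 higher and 1678 lower with each array centred on its median, and 1808 of the 3511 by at least 1.5-fold (895 higher, 913 lower). Of 49 named genes that passed, 4 lost the call when 1 array was left out, IL6, VEGFA, TRIB3 and CD163, as did the camera calls of the JAK-STAT, STAT3 target and ATF4 lists (adjusted p = 0.0509 each without the second siSCR array, and 0.0562 and 0.0531 for the last 2 without the first siRECK array). The ATF4 list also lost it without dim genes (adjusted p = 0.0541), and the pro-angiogenic list passed with the mean of all probe sets (adjusted p = 0.0283). The GAPDH 3' minus 5' value, a sign of RNA quality, was 0.37 on the arrays labelled siSCR and 0.45 on those labelled siRECK, and the correlation between these 2 groups of arrays averaged 0.966, below the 0.972 between the Hs343T and Hs606T arrays labelled siSCR. Without both deviating arrays of the invasive lines 4292 genes passed, 3470 of them among the 3511.

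**Figure D2:**
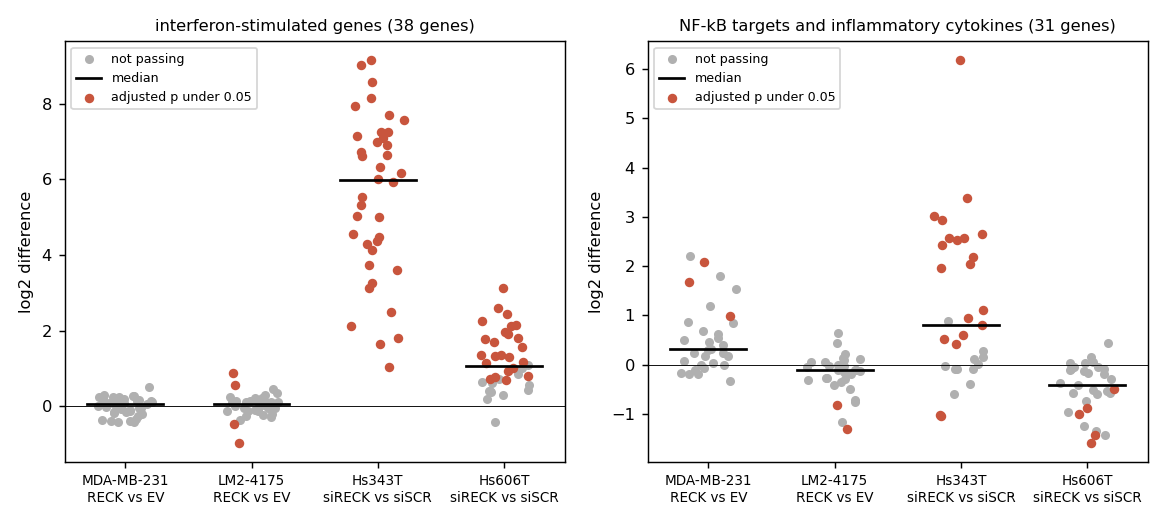
Log2 differences (vertical axis) of 38 interferon-stimulated genes and of 31 NF-kB targets and inflammatory cytokines in the 4 lines (horizontal axis), with 1 point per gene, red where the adjusted p passed, and a bar at each list's median. The interferon medians are 5.97 in Hs343T and 1.06 in Hs606T, and the NF-kB medians are 0.81 and -0.42.

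In Hs606T, interferon-stimulated genes were again higher on the arrays labelled siRECK, by less than in Hs343T. IFIT1 rose 8.83-fold (95% interval 6.86 to 11.4; log2 difference 3.14, SE 0.17, n = 2 and 2; adjusted p = 1.06e-06) and RSAD2 6.09-fold (95% interval 5.04 to 7.37; adjusted p = 5.24e-07). IFIT3 (2.45), IFIT2 (2.25), the ISG15 protease USP18 (2.16), OAS1 (2.12), RTP4 (2.04), the RNA sensor RIGI (1.97) and MX1 (1.91) followed, beside RECK. Of 38 interferon-stimulated genes 24 rose and none fell, or 33 when adjusted over the list alone, with a median of 1.06 (camera adjusted p = 5.33e-63; adjusted p = 0.0016 with an estimated correlation). The largest falls were in the heat shock gene HSPA6 (-1.62), CXCL3 (-1.58), the kynureninase KYNU (-1.57), IL1B (-1.43), HSD11B1 (-1.40), RGCC (-1.37), the ion channel TRPA1 (-1.34), CXCL5 (-1.29), MMP1 (-1.08, adjusted p = 0.0024) and the kinase MAP3K5 (-1.02).

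CXCL3, IL1B, CXCL5 and CXCL1 fell in Hs606T, while CXCL10 rose by 1.79. Of 31 NF-kB targets 5 fell and none rose, or 13 and 1 when adjusted over the list alone, with CXCL3, IL1B, CXCL1 (-0.99) and TNFAIP6 (-0.88) the largest (camera adjusted p = 1.02e-08; adjusted p = 0.213 with an estimated correlation). Of 47 pro-angiogenic factors CXCL3, IL1B, CXCL5 and CXCL1 fell and FGF1 rose, or 8 and 4 when adjusted over the list alone (camera adjusted p = 0.120). Cholesterol and lipid synthesis lay higher at a median of 0.20, with ACAT2 (0.71) the 1 gene of 22 to rise and 6 when adjusted over the list alone (camera adjusted p = 9.39e-07; adjusted p = 0.0764 with an estimated correlation). Among 21 genes of oxidative stress and metallothioneins SLC7A11 (-0.56) and MT1F (-0.37, cross-hybridising probe sets only) fell, or 10 when adjusted over the list alone (camera adjusted p = 9.39e-07; adjusted p = 0.0764 with an estimated correlation). Of 59 cell cycle genes TK1 (0.61) and NUSAP1 (0.59, probe sets differing in sign) rose, or 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.659 with an estimated correlation). IER3 (-0.63) was the 1 STAT3 target of 33 to fall, also when adjusted over the list alone (camera adjusted p = 0.156). No leukocyte marker of 18 passed, nor when adjusted over the list alone (camera adjusted p = 0.171). Of the genes fixed in advance, MMP1 apart, none passed: STAT3 differed by 0.32, IL6 by -0.60, IL6ST by -0.12, VEGFA by -0.03, CXCL8 by -0.04, PLAU by -1.05, MMP2 by -0.08, MMP9 by -0.08 and MMP14 by -0.39.

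In Hs606T 143 genes passed (97 higher, 46 lower), 93 of them by at least 1.5-fold. With its own 4 arrays alone 65 passed, and 53, 54 and 46 passed without the first siSCR, the second siSCR and the first siRECK array. With trend and robust 198 passed, and without both deviating arrays of the invasive lines 364, all 143 among them. Of 29 named genes that passed, 12 lost the call when 1 array was left out, IL1B, CXCL3 and HSPA6 among them. The cell cycle list missed its call without the second siSCR array (adjusted p = 0.0675), while the pro-angiogenic list passed without the first siRECK array (adjusted p = 0.0200) or dim genes (0.0376) and the leukocyte list without the second siRECK array (0.0483).

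Averaged over both invasive lines, the largest rise with the construct was in the stromelysin gene MMP3. It rose by 1.54 (SE 0.19, n = 4 and 4; adjusted p = 0.0022), SSX1 by 1.44, IL1B by 1.36, ENPP2 by 1.26, MMP1 by 1.10, SCG5 by 1.07, COL1A2 by 1.04 and TENM1 by 1.02. CD96 fell by 1.15, the protocadherin gene PCDH7 by 1.09, LOXL1 by 0.99, SNX10 by 0.91, HLA-DPA1 by 0.90, the stem cell receptor gene LGR5 by 0.85, SPRY1, a feedback inhibitor of growth factor signalling, by 0.82, and FABP4 by 0.81. Such a mean need not hold in both lines. For COL1A2, LOXL1 and FABP4 (LM24175 minus MDA-MB-231 response 2.34, -2.37 and -1.68) it came from LM24175, and MDA-MB-231 did not move that way. Responses also differed for HLA-DPA1 (-1.47), MMP1 (1.33), TENM1 (1.28) and ENPP2 (0.81). Neither the list of MMPs, with 3 of 24 higher and none lower (5 and 1 when adjusted over the list alone; camera adjusted p = 0.157), nor that of NF-kB targets and cytokines, with 2 of 31 higher and IL11 (-0.50, named after its value was seen) lower (4 and 1 when adjusted over the list alone; camera adjusted p = 0.169), passed. Of 34 targets of the unfolded protein response and of ATF4 the serine synthesis genes PSAT1 (0.57) and PHGDH (0.51) rose, or 12 when adjusted over the list alone (camera adjusted p = 2.36e-04; adjusted p = 0.749 with an estimated correlation), and the camera call ended without the first MDA-MB-231 empty-vector array (adjusted p = 0.280). MMP9 (0.69, adjusted p = 0.0517), STAT3 (-0.06), IL6 (0.25), IL6ST (0.04), VEGFA (-0.05), CXCL8 (0.45), PLAU (-0.23), MMP2 (-0.30) and MMP14 (0.24) did not pass. In all 288 genes passed (198 higher, 90 lower), 62 of them by at least 1.5-fold. With these 8 arrays alone 24 passed, and 569, 93, 84 and 95 passed without the second MDA-MB-231 empty-vector array, the first MDA-MB-231 RECK array, and the first and second LM24175 empty-vector arrays. Without both deviating arrays 557 passed.

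Averaged over both poorly invasive lines, the arrays labelled siRECK held higher antiviral transcripts. RSAD2 rose by 5.81 (SE 0.09, n = 4 and 4; adjusted p = 8.52e-13), IFIT1 by 5.54, CXCL10 by 5.18, MX1 by 5.03, CXCL11 by 4.88, IFI44L by 4.68, IFIH1 by 4.63 and IFIT3 by 4.53. PLAU fell by 2.10 (SE 0.19; adjusted p = 7.86e-06), CERK by 1.96, RGCC by 1.95, SLC7A11 by 1.66, BUB1B by 1.64, CNIH3 by 1.63, ZMAT3 by 1.63 and ADGRA3 by 1.61. Each of these rises and falls was smaller in Hs606T than in Hs343T, by a difference that passed. For CXCL11 and ZMAT3 (Hs606T minus Hs343T response -8.52 and 3.43) the mean came mostly from Hs343T, and ZMAT3 was not lower in Hs606T. All 38 interferon-stimulated genes rose, in the list alone too, with a median of 3.30 (camera adjusted p = 8.0e-72; adjusted p = 9.65e-04 with an estimated correlation). STAT3 rose by 0.65 (adjusted p = 1.95e-05) and MMP1 fell by 0.69 (adjusted p = 3.65e-04). IL6 (0.26), IL6ST (-0.04), VEGFA (-0.49), CXCL8 (-0.21), MMP2 (-0.03), MMP9 (-0.16) and MMP14 (-0.25) did not pass. In all 2572 genes passed (1168 higher, 1404 lower), against 1240 higher and 1141 lower with each array centred on its median, and 658 of the 2572 by at least 1.5-fold (431 higher, 227 lower). Which direction held more genes thus depended on these choices.

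Over all 4 lines, the arrays labelled as having more RECK (the construct, and siSCR) were set against those labelled as having less. By the labels, IFIT1 fell by 2.85 (SE 0.08, n = 8 and 8; adjusted p = 5.67e-10), RSAD2 by 2.73, OAS1 by 2.60, MX1 by 2.57, CXCL10 by 2.55, RTP4 by 2.37, IFIT2 by 2.30 and IFIT3 by 2.29. IL1B rose by 1.29 (SE 0.15; adjusted p = 8.67e-05), the bone morphogenetic protein BMP2 by 1.18, MMP3 by 1.05, CERK by 0.95, SLC7A11 by 0.94, PLAU by 0.93, ZMAT3 by 0.93 and MMP1 by 0.90. With the construct CERK and PLAU were not higher on average, so their rises came from the siRNA lines. Those of SLC7A11 and ZMAT3 came mostly from Hs343T. All 38 interferon-stimulated genes fell, also when adjusted over the list alone (camera adjusted p = 2.87e-73; adjusted p = 8.97e-04 with an estimated correlation). This fall came from the siRNA lines, since with the construct in both invasive lines 1 of the 38 rose, 1 fell and the median was 0.01 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.845). Of 33 STAT3 targets 4 rose and 4 fell, or 4 and 5 when adjusted over the list alone (camera adjusted p = 0.719). They were led by MMP9 (0.42), STAT3 itself (-0.35), FOS (-0.35) and BIRC5 (0.29), and the median (0.01) and mean (0.02) lay above 0 while camera read the list as lower. Of 47 pro-angiogenic factors 11 rose and 11 fell, or 11 and 12 when adjusted over the list alone (camera adjusted p = 0.921), with IL1B, FGF1 (-0.99), PLAU and CXCL3 (0.84) the largest. Their median (0.07) and mean (0.06) also lay above 0 against a lower camera direction. MMP14 rose by 0.25 (adjusted p = 0.0204), and IL6 (0.00), IL6ST (0.04), VEGFA (0.22), CXCL8 (0.33) and MMP2 (-0.14) did not pass. In all 1820 genes passed (952 higher, 868 lower), against 861 higher and 876 lower with each array centred on its median and 1122 and 831 with quantile normalization, and 194 of the 1820 by at least 1.5-fold (38 higher, 156 lower). As RECK was higher on the arrays labelled siRECK, the fit was repeated with the sign of the siRNA lines turned, which gave 1692 genes, and without Hs343T, which gave 236. Without both deviating arrays CXCL8 (0.31) and VEGFA (0.25) passed. These repeats were chosen after the data were seen.

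The responses of the 2 invasive lines differed in lipid synthesis. The LM24175 response minus the MDA-MB-231 response was negative for 14 of 22 cholesterol and lipid synthesis genes and positive for none (17 and 1 when adjusted over the list alone), with a median of -0.84 (camera adjusted p = 1.08e-17; adjusted p = 0.0071 with an estimated correlation). The list's median level was 9.13 with vector and 9.43 with construct in MDA-MB-231, and 9.71 and 9.26 in LM24175. This difference, the 2 responses and the gap between the empty-vector lines rest on the same empty-vector arrays. They are therefore not separate evidence, and opposite effects of the construct cannot be told apart from a gap between the empty-vector arrays. SLCO4C1 (-3.32), SHANK2 (-2.81, probe sets differing in sign), SCD (-2.59), the endothelial lipase LIPG (-2.50), LOXL1 (-2.37), CXCL3 (-2.16), ST6GAL1 (-1.92, probe sets differing in sign) and C1S (-1.80) differed most in that direction. COL1A2 (2.34), CST6 (2.23), HMGN5 (2.18), DCBLD2 (1.94), the vitamin D hydroxylase CYP24A1 (1.74), NDP (1.69), CCDC69 (1.68) and AKR1C2 (1.68, cross-hybridising probe sets only) differed most in the other. MMP1 differed by 1.33 (SE 0.20; adjusted p = 0.0062), while STAT3 (-0.09), IL6 (-0.74), IL6ST (-0.32), VEGFA (-0.69), CXCL8 (-1.48), PLAU (-0.24), MMP2 (-0.11), MMP9 (0.82) and MMP14 (0.26) did not pass, MMP14 doing so without both deviating arrays (0.60, adjusted p = 0.0259). In all 435 genes passed (197 higher, 238 lower), against 230 and 183 with each array centred on its median. Of 17 named genes that passed, 13 lost the call with these 8 arrays alone. Some also lost it when 1 array or both deviating arrays were left out. With these 8 arrays alone 21 passed, and leaving out 1 array gave from 123 genes (first LM24175 empty-vector array) to 1411 (second MDA-MB-231 empty-vector array), with 139, 166, 207 and 936 without the second LM24175 empty-vector, first MDA-MB-231 RECK, first LM24175 RECK and second LM24175 RECK array.

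**Figure D3:**
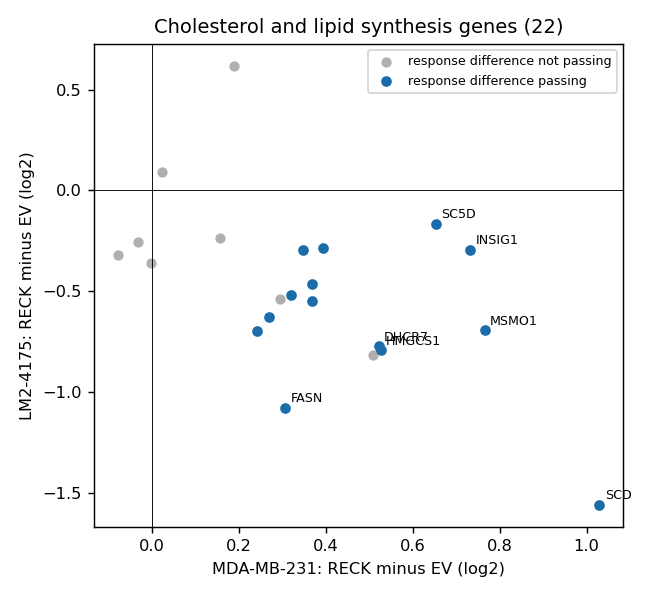
Log2 difference of RECK construct minus empty vector in MDA-MB-231 (horizontal axis) and LM24175 (vertical axis) for 22 cholesterol and lipid synthesis genes, with 1 point per gene, blue where the difference between the lines passed. SCD lies at 1.03 and -1.56, and 14 genes passed, all with the lower value in LM24175.

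The responses of the 2 poorly invasive lines differed in size and, for some genes, in direction. The Hs606T response minus the Hs343T response was negative for all 38 interferon-stimulated genes (all 38 when adjusted over the list alone), with a median of -4.36 (camera adjusted p = 2.37e-57; adjusted p = 0.0022 with an estimated correlation). CXCL11 (-8.52), IFNB1 (-8.25), ISG20 (-6.86), CXCL10 (-6.77), TNFSF10 (-6.75), CCL5 (-6.59), RSAD2 (-6.42) and the tryptophan-degrading enzyme IDO1 (-6.29) differed most. In the other direction were ZMAT3 (3.43), the mitotic genes DLGAP5 (3.19), TOP2A (2.87) and ASPM (2.71), CERK (3.18), DLEU1 (2.77), NT5DC2 (2.72) and APPL2 (2.69). For KYNU, named here after its values were seen, the difference was 0.74 in Hs343T and -1.57 in Hs606T, and both passed, as did that between them (-2.31, adjusted p = 1.85e-07). The Hs606T response was lower than the Hs343T response for 19 of 31 NF-kB targets and higher for none (21 and 0 when adjusted over the list alone; camera adjusted p = 9.56e-15; adjusted p = 0.229 with an estimated correlation). It was higher for 41 of 59 cell cycle genes and lower for none (44 and 0 when adjusted over the list alone; camera adjusted p = 3.21e-20; adjusted p = 0.229 with an estimated correlation). PLAU (2.09, adjusted p = 0.0019), STAT3 (-0.64, adjusted p = 0.0038), IL6 (-1.71, adjusted p = 0.0121) and MMP1 (-0.78, adjusted p = 0.0161) passed, while IL6ST (-0.14), VEGFA (0.92), CXCL8 (0.34), MMP2 (-0.11), MMP9 (0.17) and MMP14 (-0.27) did not. In all 2436 genes passed (1393 higher, 1043 lower), against 1143 higher and 1167 lower with each array centred on its median.

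Between lines, 24 overlaps of calls were tested, 4 for each of 6 pairs, with 2-sided Fisher's exact tests adjusted over the 24; genes are not independent replicates. Hs343T and Hs606T shared 57 higher genes against 11.6 expected for independent lists (adjusted p = 5.87e-27) and 19 lower genes against 8.0 (adjusted p = 4.01e-04), and their log2 differences correlated across genes at r = 0.262 (rho = 0.054). LM24175 and Hs343T overlapped beyond independence in all 4 combinations of direction, with 74 higher in both against 49.2 expected, 102 lower in both against 68.0, 123 higher then lower against 71.4 and 81 lower then higher against 46.8 (largest adjusted p = 7.92e-04). An overlap that passes is thus not evidence of a shared direction. Also past 0.05 were 10 genes higher in MDA-MB-231 and lower in Hs343T (4.69 expected; adjusted p = 0.0384), and 12 higher (3.33 expected; adjusted p = 4.01e-04) and 6 lower (1.504 expected; adjusted p = 0.0086) in both LM24175 and Hs606T. IL1B, CXCL3, CXCL1 and KYNU were higher with the construct in MDA-MB-231 and lower on the arrays labelled siRECK in Hs606T, 4 genes against 0.104 expected (adjusted p = 1.89e-05). With the MDA-MB-231 arrays alone 0 genes passed. On its deviating first empty-vector array IL1B lay -0.67 and CXCL3 -1.03 from the replicate, which enlarges their rises. The Hs606T calls of IL1B and CXCL3 also depended on single arrays, and the direction there is that of the labels, opposite to the measured RECK level. MDA-MB-231 and LM24175 shared 3 higher and 1 lower genes (adjusted p = 0.116 and 0.241), and 5 genes, HOXB7, DHCR7, KYNU, LRP8 and MSMO1, rose in the first and fell in the second (adjusted p = 0.0043). The names HOXB7 and LRP8 were chosen after their values were seen. The differences of these 2 lines correlated at r = -0.128 across genes, or 0.0985 without the first and -0.292 without the second LM24175 RECK array and 0.0073 without the first MDA-MB-231 empty-vector array.

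With the empty vector, LM24175 had more transcripts of SPARC, VCAM1 and IL13RA2 than its parent line. SPARC, a matrix glycoprotein, was 175-fold higher in LM24175 (95% interval 139 to 220; log2 difference 7.45, SE 0.15, n = 2 and 2; adjusted p = 3.89e-11), the adhesion molecule VCAM1 105-fold (95% interval 55.3 to 200; log2 difference 6.71) and the decoy receptor IL13RA2 64.0-fold (95% interval 49.2 to 83.4). MAGEB2 (5.69), the laminin chain LAMA4 (4.96), PTPRN2 (4.85), CADM1 (4.44) and TNFSF4 (4.41) were also higher. DMD, the dystrophin gene (-4.53), the cancer-testis genes MAGEA11 (-3.84) and MAGEC1 (-3.44), BCHE (-3.53), the protease gene ADAMTS1 (-3.375), HLA-DRB4 (-3.30), ADGRF5 (-3.23) and the tight junction gene CLDN4 (-3.16) were lower. IL6 (3.71, SE 0.30; adjusted p = 6.13e-06) and MMP2 (3.02; adjusted p = 6.33e-07) were higher, MMP1 (-1.58; adjusted p = 1.41e-05) and MMP14 (-0.94; adjusted p = 2.79e-04) lower, and STAT3 (0.18), IL6ST (0.22), VEGFA (0.01), CXCL8 (0.37), PLAU (-0.25) and MMP9 (-0.43) did not pass.

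Of 19 lung metastasis genes of MDA-MB-231 derivatives 10 were higher and 2 lower in LM24175, or 11 and 2 when adjusted over the list alone, led by SPARC, VCAM1, IL13RA2 and MMP2 (camera adjusted p = 4.48e-06; adjusted p = 0.136 with an estimated correlation). Some of that list was chosen in such derivatives, so its direction is not independent evidence. Of 44 matrix genes 20 were higher and none lower, or 21 and 3 when adjusted over the list alone, with SPARC, LAMA4, COL1A1 (3.21, probe sets differing in sign) and COL6A1 (3.07) the largest (camera adjusted p = 1.78e-08; adjusted p = 0.159 with an estimated correlation). Cholesterol and lipid synthesis genes were higher, 17 of 22, or 18 when adjusted over the list alone, with MSMO1 (1.22), INSIG1 (1.09), HMGCS1 (1.02) and SCD (0.99) in front (camera adjusted p = 5.33e-12; adjusted p = 0.0257 with an estimated correlation). The same empty-vector arrays enter the opposite shifts of this list with the construct, so these results are not independent. Of 30 TGF-beta targets 11 were higher and 4 lower, the same counts when adjusted over the list alone, led by COL1A1, ID3 (2.18), TAGLN (1.80) and FN1 (1.75), with camera adjusted p = 0.0020 and adjusted p = 0.337 with an estimated correlation. That camera call ended without the first MDA-MB-231 empty-vector array (adjusted p = 0.100). In all 2489 genes passed (1181 higher, 1308 lower), 1144 of them by at least 1.5-fold. With these 4 arrays alone 1169 passed, and 1466 and 1430 passed without the first and second LM24175 empty-vector array. Without both deviating arrays VEGFA (-0.37, adjusted p = 0.0334) and PLAU (-0.75, adjusted p = 0.0017) passed and the TGF-beta list did not (adjusted p = 0.0926), and on the first MDA-MB-231 empty-vector array IL1B, CXCL3, CXCL8, VEGFA and PLAU lay below their replicate.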

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

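The tests of RECK against the labels, of the interferon response and of the deviating arrays were chosen after those results were seen; the counts of other splits of the arrays were chosen before.

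RECK was higher on the arrays labelled siRECK in both siRNA lines. A fault of the probe set with the highest level is argued against only weakly in Hs343T, where another RECK probe set was also higher (0.4581). That other probe set is open to cross-hybridisation and was 1.37-fold higher, against 44.5-fold for the first. The third probe set's difference of 0.27 did not pass. In Hs606T the cross-hybridising probe set's difference of 0.1717 did not pass and the question stays open. Exchanged labels in both lines may account for the direction. The lines differed in RECK by 2.8974 on the arrays labelled siSCR and by 0.1774 (Hs343T the higher) on those labelled siRECK, and with no untreated array used here, exchange and a real rise cannot be told apart. A rise of RECK itself under this siRNA remains an untested biological explanation.

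Interferon-stimulated genes were higher on the arrays labelled siRECK, by a median of 5.97 in Hs343T and 1.06 in Hs606T. RNA of leukocytes is argued against in Hs343T, where 18 leukocyte markers had a median of -0.0729 and the 1 that passed, CD163, fell. That those Hs343T arrays hold another of the lines is argued against less firmly: 152 of 199 genes that part the siSCR arrays of the lines lay nearer to Hs343T (0.7638; exact 95% interval 0.699 to 0.821 across genes, which are not independent), and the Hs343T siRECK group mean correlated at 0.9676 with that of Hs343T siSCR and at 0.9562 with that of Hs606T siSCR. The Hs343T siSCR arrays, however, correlated more with the Hs606T siSCR arrays (mean 0.9718) than with the Hs343T siRECK arrays (0.9663). A bound of 0.9 set beforehand was not reached, and that the interval lies above 0.5 was taken as deciding only after the value was seen. The test of these genes covered neither a mixture nor the invasive lines. Arrays of the invasive lines correlated with the Hs343T siRECK arrays at 0.857 to 0.872. A response to the transfected RNA itself, and not to RECK, may account for it and stays open: the same genes had a median of 0.0644 with the construct in LM24175, where the RECK probe sets did not rise, and no second siRNA was used here.

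The first MDA-MB-231 empty-vector array and the first LM24175 RECK array deviated together from their replicates (r = 0.486, next largest pair in size -0.1215), with GDF15 at -2.59 and -2.32 and PTGS2 at -2.59 and -2.01. RNA degradation is argued against by GAPDH 3' minus 5' values that differed from the replicates by -0.0753 at most in size. The ACTB 3' minus 5' values, not part of that test, lay further from the replicates. They were 0.71 against 0.96 for the first array and 0.88 against 0.98 for the second, lower on both deviating arrays. RNA of LM24175 mixed into the first array, other than that of the array deviating with it, is argued against as the whole cause. A mixture lies between its parts, yet of 27 genes that deviated by 2-fold or more in 1 direction on both arrays, 23 lay on the first array over 0.5 log2 units outside the range of its replicate and the other LM24175 arrays (share 0.8519; exact 95% interval 0.663 to 0.958 across genes, which are not independent). These genes were picked for deviating on the same arrays, so the share and its interval speak for them alone. RNA of MDA-MB-231 mixed into the second may contribute and stays open, with 19 of 27 outside the range (0.7037; interval 0.498 to 0.863), as does RNA of 1 of the 2 arrays in the other, which was not tested. A median shift towards the other line over 31 genes, tried first, was -0.0456 (quartiles -0.370 and 0.286) on the first array and 0.2346 (quartiles 0.0482 and 0.637) on the second. It decides neither, though on the second array both quartiles lay towards the other line. A shared culture state is an untested biological explanation.

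Over both invasive lines, 5 of 34 splits of the 8 arrays gave at least 288 genes, with 698 the highest other, so chance was not excluded. Of the 4 other splits, that with 435 genes is the difference between the LM24175 and MDA-MB-231 responses. It and the others, with 289, 321 and 698 genes, put both deviating arrays on 1 side. Leaving both arrays out kept the count for that difference between responses within 1.5 times. Whether those arrays account for the others was not tested. Over both poorly invasive lines only the real split of 34 gave 2572 genes. The highest other, 2436, is the difference between the Hs606T and Hs343T responses. Over all 4 lines 100 of the possible splits were drawn, the real one included, and only that gave 1820 (highest other drawn 1615). The grouping with the sign of the siRNA lines turned gave 1692, and without Hs343T 236 genes passed. A split that mixes the arrays of a group puts the group differences into the spread, and the median of the other splits was 0 genes in both comparisons. Such splits call few genes whatever the cause, so they cannot exclude chance. They also say nothing of separate cultures, since the arrays of a group may be technical repeats. In each set of 34, 1 further split, which parts the lines, could not be fitted.

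The responses of the invasive lines differed by the test of the difference, LM24175 minus MDA-MB-231, in 435 genes and in the cholesterol list (median -0.8371). Among genes named for either line the higher values were in ADIRF (1.29), AKR1C1 (1.44), AKR1C2 (1.68), AKR1C3 (1.63), COL1A2 (2.34), COL3A1 (1.58), COL6A3 (1.08), ENPP2 (0.81), HMGN5 (2.18), LYPD1 (1.51), MMP1 (1.33), TCN1 (1.52), TENM1 (1.28) and VSNL1 (0.98). The lower values were in AUTS2 (-1.50), C4BPB (-1.50), CSF1 (-1.04), CXCL1 (-1.03), CXCL3 (-2.16), DHCR7 (-1.30), FABP4 (-1.68), FASN (-1.39), HLA-DPA1 (-1.47), HMGCS1 (-1.32), IL11 (-1.60), INSIG1 (-1.03), LOX (-1.76), LOXL1 (-2.37), MIR3916 (-1.70), MSMO1 (-1.46), MTHFD2 (-0.65), PLOD2 (-1.11), S100P (-1.50), SC5D (-0.82), SCD (-2.59), SHANK2 (-2.81) and SLCO4C1 (-3.32).

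The responses of the poorly invasive lines differed likewise, Hs606T minus Hs343T, in 2436 genes and in the interferon list (median -4.3562). Higher values were in ACAT2 (0.97), ADGRA3 (2.4), BIRC5 (1.92), BUB1B (2.29), CDK1 (2.48), CERK (3.18), CNIH3 (2.35), CPEB1 (2.19), DLGAP5 (3.19), FAM171A1 (2.53), LAMA4 (0.85), NT5DC2 (2.72), NUSAP1 (2.4), PLAU (2.09), RGCC (1.18), SLC7A11 (2.21), TK1 (0.87), TOP2A (2.87) and ZMAT3 (3.43). Lower values were in ADM (-1.68), ATF3 (-3.50), CCL2 (-3.10), CCL5 (-6.59), CSF1 (-2.98), CXCL1 (-0.91), CXCL10 (-6.77), CXCL11 (-8.52), CXCL5 (-1.33), EDN1 (-2.06), FGF1 (-1.62), FOS (-1.91), HSD11B1 (-0.84), ICAM1 (-3.15), IFI44L (-5.76), IFIH1 (-6.12), IFIT1 (-4.80), IFIT2 (-4.49), IFIT3 (-4.17), IFNB1 (-8.25), IL6 (-1.71), JAG1 (-1.78), JAK2 (-2.47), JUNB (-1.60), KYNU (-2.31), MAP3K5 (-1.65), MMP1 (-0.78), MT1F (-0.50), MX1 (-6.25), OAS1 (-4.80), OASL (-5.90), RECK (-3.07), RIGI (-4.36), RSAD2 (-6.42), RTP4 (-4.90), SOCS1 (-2.85), SOCS2 (-1.82), STAT3 (-0.64), TGFA (-1.05), TNFAIP6 (-1.31), TNFSF10 (-6.75), TRPA1 (-3.85), TYMP (-2.40), USP18 (-3.85) and VCAM1 (-4.79).

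Of 3151 probe sets with no single gene symbol, left out of the comparisons above, 6 passed in MDA-MB-231, 87 in LM24175, 602 in Hs343T and 16 in Hs606T.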

How the results depend on the processing

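Turning the sign of the siRNA lines, leaving out Hs343T and leaving out both deviating arrays were chosen after the results were seen. All 10 counts of genes stayed within 1.5 times under quantile normalization, centring on the median and the mean of all probe sets. RECK, read by the probe set with the highest level, kept its direction and its call in both siRNA lines under the alternatives, and with the mean of its 3 probe sets the differences shrank to 2.07 in Hs343T and 0.82 in Hs606T (adjusted p = 8.97e-04). Its 2 other probe sets did not pass in Hs606T, and 1 of them was lower there (-0.10). Of 271 passing pairs of named gene and comparison, none changed direction under an alternative. With all probe sets tested alone, however, each gene was still read by the probe set with the highest level, and in 15 of these pairs another probe set of the gene had the opposite sign. The 1 reversal was VEGFA between the empty-vector lines, 0.01 (not passing) against -0.37 without both deviating arrays. Of those arrays, only the first MDA-MB-231 empty-vector array enters this comparison. It read VEGFA at -0.77 from its replicate, so leaving it out lowers the difference.

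In MDA-MB-231 the count of 33 became 61 with dim genes left out, 53 with all probe sets tested alone and 81 with trend and robust. With only the arrays compared, which leaves 2 or 4 residual degrees of freedom, the counts were 0 in MDA-MB-231, 153 in LM24175, 65 in Hs606T, 24 over both invasive lines, 21 for the difference between their responses and 1169 between the empty-vector lines. With the replicate number as a block the same counts were 1, 432, 68, 96 and 148 in the first 5. The replicate numbers do not pair the arrays, whose deviations correlated at -0.0149 in MDA-MB-231, -0.0367 in LM24175, -0.0505 in Hs343T and 0.0106 in Hs606T. A 1.5-fold minimum left 343 genes in LM24175, 1808 in Hs343T, 93 in Hs606T, 62 and 658 over both invasive and both poorly invasive lines, 194 over all lines and 1144 between the empty-vector lines, as it must. All probe sets tested alone gave 5479 in Hs343T, of more features tested, and trend and robust gave 671 for the difference between the invasive lines. Without both deviating arrays 117 genes passed in MDA-MB-231 and 557 over both invasive lines, and also more in lines that hold neither array, 364 in Hs606T and 4292 in Hs343T. Without Hs343T 236 passed over all lines. In lines that hold neither deviating array the differences cannot change when both are left out. Their higher counts therefore come from the spread pooled over the groups. The 2 groups concerned had the largest SDs of replicate differences, 0.312 and 0.272, and they enter the spread of every comparison in the main fit. Apart from this and from settings that test fewer or more features, the cause was not tested.

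Leaving out 1 array, with the lone array of its group assumed to vary like the other groups, gave 3 to 681 genes in MDA-MB-231, 276 to 841 in LM24175, 2633 to 2669 in Hs343T, 46 to 101 in Hs606T, 84 to 569 over both invasive lines, 1950 to 2238 over both poorly invasive lines, 1366 to 2090 over all, 123 to 1411 and 1851 to 2108 for the differences between responses, and 1430 to 2413 between the empty-vector lines. No detection calls were used, so a low level cannot be told from background, and folds from low levels, such as IFNB1 at 4.26 on the Hs343T siSCR arrays, may be compressed; leaving out dim genes changed the Hs343T camera call of the ATF4 list (adjusted p = 0.0541).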

Other observations

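No test was added for this part, and the gene lists below were picked from the 29 after their results were seen. The poorly invasive lines carried high levels of fibroblast and matrix transcripts. The collagen I chain COL1A1 read 12.46 ± 0.01 (SD, n = 2) in Hs343T and 12.92 ± 0.01 (SD, n = 2) in Hs606T on the arrays labelled siSCR, against 4.44 ± 0.80 (SD, n = 2) in MDA-MB-231 and 7.65 ± 0.04 (SD, n = 2) in LM24175 with empty vector. In the same order the collagen III chain COL3A1 read 13.84, 14.36, 3.97 and 3.92, the growth factor receptor PDGFRA 12.06, 12.84, 3.53 and 4.02, the fibroblast activation protein FAP 9.27, 11.63, 4.06 and 4.40 and the matrix protein POSTN 11.66, 13.82, 3.40 and 3.08. The keratins KRT8 (6.84, 6.09, 9.75 and 10.06) and KRT18 (10.18, 8.34, 12.77 and 12.78), read by cross-hybridising probe sets, lay the other way. The median level of fibroblast and mesenchymal markers was 11.66, 12.31, 4.92 and 5.77, and that of epithelial markers 5.54, 5.32, 6.60 and 6.23. These levels were not tested, since line and kind of treatment go together.

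Between the empty-vector lines, LM24175 against MDA-MB-231, 13 of 31 NF-kB targets were higher and none lower, or 16 and 1 when adjusted over the list alone (camera adjusted p = 4.73e-07; adjusted p = 0.400 with an estimated correlation). Members such as PTGS2, CXCL3, CXCL8 and IL1B lay below their replicate on the deviating first MDA-MB-231 empty-vector array, which raises their differences here. This list was not tested without that array. Of 11 histone genes 8 were lower and none higher, or 10 when adjusted over the list alone, with a median of -0.71 (camera adjusted p = 1.76e-05; adjusted p = 0.258 with an estimated correlation). Of 27 fibroblast and mesenchymal markers 12 were higher and 1 lower, or 14 and 3 when adjusted over the list alone (camera adjusted p = 3.16e-05; adjusted p = 0.136 with an estimated correlation). In Hs606T, 3 of 19 lung metastasis genes were lower on the arrays labelled siRECK and none higher, or 6 and 2 when adjusted over the list alone (camera adjusted p = 0.0044; adjusted p = 0.213 with an estimated correlation).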
